A study of Arabidopsis thaliana with 18 samples.

How the data were processed

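RNA from the aerial parts of Landsberg erecta seedlings, wild type and gcn2, was hybridized to Affymetrix ATH1 arrays, with 3 replicates each of polysomal, non-polysomal and total RNA. Per the labels, seedlings grew for 10 days at 22 °C under 16 h of light at 80 µmol per square metre and second on plates whose agar (0.8%) held sucrose at 1%. Groups and replicate numbers were taken from the sample titles. The values used were the deposited table of log2 expression values per probe set, which the authors made before deposit. RMA, affy and MAS5 are named in the submitters' processing notes with no role and no version, so that the summarization and background steps behind the values are not given in the sources used here. The arrays' medians lay between 5.05 and 5.18, so the deposited values share a common scale, and a transcript's difference between RNA types is relative to the array-wide level. A fixed total signal per array hides any change in the amount of RNA per fraction.

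The table held 22810 probe sets. The 64 control probe sets were left out of the tests, and 22746 were tested. Probe sets were named through the platform annotation given for the series, in which 13513 tested probe sets had exactly 1 gene, 503 had several and 8730 were not listed and are unnamed here. Of those with 1 gene, 13436 were matched by gene number to a RefSeq gene table of the TAIR10.1 assembly, which served for names and for the order of neighbouring genes and not for coordinates. They stood for 13355 loci, of which 1557 had a symbol, and 111 loci were named by a synonym. Plastid genes (69 probe sets) were taken from the table's plastid chromosome, and mitochondrial genes (23 probe sets) from the mitochondrial symbols. Where a locus had several probe sets, the one with the highest mean over all 18 arrays stood for it. GCN2 and the erecta gene were not analysed here.

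All pairs of arrays were compared, and 0 of 153 pairs held identical values. Each comparison was a contrast in a group-means model of all 18 arrays and 6 groups in limma 3.58.1 under R 4.3.3, with 12 residual degrees of freedom, empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05, without a filter or a fold threshold. The 6 comparisons were gcn2 against wild type in total, polysomal and non-polysomal RNA, polysomal against non-polysomal RNA in each genotype, called loading, and the difference in loading between genotypes. Errors of log2 differences are moderated standard errors, and those of group levels are SD over 3 arrays. With 3 against 3 arrays, a permutation test of a single value cannot go below 0.1. Differences of transcripts between groups of 3 were therefore tested in limma.

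Whether equal replicate numbers pair arrays was checked on the deviations from the group means. Arrays of the same number correlated at 0.184 to 0.588 in all 6 pairs of fraction groups, above 0.1, so the numbers pair the polysomal and non-polysomal arrays. Wild-type total RNA was paired in this way with 3 of the 4 fraction groups and gcn2 total RNA with 0 of 4. Between the genotypes the total RNA correlations were 0.0981, 0.0157 and 0.429, so that number 3 exceeded 0.1 and numbers 1 and 2 did not, and nothing was renumbered. The replicate number was used as a block in a second fit of 18 arrays with 10 residual degrees of freedom. That fit also pairs the total RNA arrays, which the check did not bear out for gcn2. A blocked fit of the 12 fraction arrays alone, where the numbers paired, was added after seeing the data.

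The 10 transcripts with a symbol and the largest change per direction were named among those past the threshold whose replicates did not overlap. Where a direction had fewer than 3, the 5 smallest p-values in it were given as values that did not pass, and up to 4 members of each list were named by the size of the moderated statistic. Loci and probe sets without a symbol fall outside this rule.

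Of 27 gene lists, 11 had at least 5 measured members and were tested with camera, with a preset inter-gene correlation of 0.01 and with an estimated one. These were plastid-encoded and mitochondrion-encoded genes, nuclear-encoded photosystem proteins, histones, amino acid biosynthesis, the unfolded protein response, jasmonate and wounding, the reactive oxygen response, autophagy, genes with conserved upstream open reading frames, and anthocyanin and flavonoid synthesis. A locus counts as measured only where a probe set was annotated to it alone, so most lists are parts of what they name. Measured were 7 of 43 photosystem loci, 8 of 24 histones, 6 of 97 for amino acid biosynthesis, 6 of 30 for the unfolded protein response and 5 of 36 for jasmonate. For the reactive oxygen response they were 5 of 37, for autophagy 10 of 27, for upstream open reading frames 6 of 24 and for anthocyanin 5 of 20. Lists with 1 to 4 measured members were given as single genes, and the lists of plastid ribosomal proteins, proteasome subunits, elongation factors and nitrate genes had 0 measured members. In these lists ATB2 and CHI matched genes (AT1G60710 and AT2G43570) other than those meant, and EIN3 was included in error, so an alternative leaves out these 3. RPS13, in a list too short to be tested as a set, matched AT1G77750, which is not a cytosolic ribosomal protein.

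The alternatives were the replicate block, a block of genotype and number together, only the arrays of the compared groups, quantile normalization over all arrays or within each RNA type, median centring, leaving out probe sets below the 40th percentile of mean signal, a trended and robust prior, array weights, a 2-fold threshold, polysomal over total RNA as loading, other correlations and probe set rules for the lists, and leaving out each array in turn. Centring on the BioB and BioC controls, the block on 12 arrays and the lists without mismatched members were added after seeing the data. The scripts were tested on simulated data with 200 of 22746 probe sets changed. In total RNA 11.9%, 88.1% and 100% of changes of 0.5, 1 and 2 on the log2 scale were recovered, and for the difference in loading 1.49%, 43.3% and 100%. The simulated noise was independent between arrays, whereas fraction arrays of the same number deviated together. With fewer changed probe sets than 200 the adjustment is stricter, so these shares are not the power of the real comparisons.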

Results

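Transcript levels were measured with Affymetrix ATH1 arrays in Arabidopsis thaliana seedlings of the Landsberg erecta line, in wild type and in gcn2, a mutant of the protein kinase GCN2, which phosphorylates a translation initiation factor when amino acids run short. The aerial parts of 10-day-old seedlings were taken 4 h after the lights came on, and their lysates were separated on sucrose gradients. RNA from the 6 bottom fractions was pooled as polysomal RNA, which holds transcripts carrying several ribosomes, and RNA from the 6 top fractions as non-polysomal RNA. Total RNA was measured as well, so that the 18 arrays fell into 6 groups of 3 replicates. The deposited log2 signals ran from 1.68 to 14.3, and the medians of the arrays lay between 5.05 and 5.18. Arrays of the same group correlated at 0.974 to 0.994 over all probe sets. The first principal component held 49.6% of the variance and placed all 6 non-polysomal arrays apart from the other 12. The number of arrays limits the precision of every value below. The labels do not say that the replicates came from separately grown cultures, so the p-values measure the spread between these samples. GCN2 and the erecta gene were not analysed here, so no transcript checks the genotype labels.

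The control probe sets differed between the RNA types. The BioB and BioC hybridization controls are bacterial transcripts, and the sources used here give neither the step at which they were added nor the amount. They had higher signals on the non-polysomal than on the polysomal array in 6 of 6 gradients. They exceeded the polysomal level by 0.89 ± 0.23 on the log2 scale (SD, n = 6, exact two-sided sign-flip test p = 0.03125, the smallest this number of gradients allows). Their group means were 9.06 ± 0.38 in wild-type polysomal and 9.99 ± 0.12 in wild-type non-polysomal RNA, and 9.31 ± 0.21 and 10.2 ± 0.21 in gcn2 (SD, n = 3 each). The Actin, GAPDH and ubiquitin control transcripts, which carry probe sets at both ends, had a larger excess of 3′ over 5′ signal in the fractions than in total RNA. The difference was 0.97 between the fraction and the total RNA arrays, without overlap (exact two-sided permutation test of the means of 6 gradients against 6 total RNA arrays, p = 0.00216). Both tests take the gradients as independent, although those of the same number also deviated together. The excess was 2.28 ± 0.12 in wild-type total RNA, 2.91 ± 0.16 in wild-type polysomal RNA and 3.24 ± 0.31 in wild-type non-polysomal RNA, and 2.22 ± 0.05, 2.99 ± 0.28 and 3.72 ± 0.42 in gcn2 (SD, n = 3 each).

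The comparison of gcn2 with wild type in total RNA asked which transcripts differed in level without regard to ribosomes. QQS (AT3G30720), an orphan gene known for its effect on starch, was the only transcript with a gene symbol that rose in gcn2, by 1.52 on the log2 scale (SE 0.22, n = 3 per group, limma adjusted p = 0.00669). It rose together with 7 others that have no symbol, and the loci among them were chosen after their values were seen. AT1G58025 rose by 4.14 (SE 0.37), from 4.71 ± 0.49 to 8.85 ± 0.08 (SD, n = 3 each), AT4G03156 by 2.37 (SE 0.30), an unannotated probe set by 2.29 (SE 0.26) and the pseudogene AT1G35650 by 1.72 (SE 0.16). AT3G30200 rose by 1.17 (SE 0.17), AT1G12000 by 1.07 (SE 0.17) and another unannotated probe set by 1.03 (SE 0.15). In wild-type total RNA QQS (3.12), AT4G03156 (2.23), the unannotated probe set at 2.29 (2.91), AT1G35650 (2.75) and AT3G30200 (2.66) lay below the lower quartile of every array (3.21 to 3.52). Their values set gcn2 signals against signals near background and are lower bounds. In limma, these 8 of 22746 probe sets passed an adjusted p of 0.05, all higher in gcn2, in 3 of 3 arrays above all 3 wild-type arrays. With no transcript called lower, 566 probe sets had an unadjusted p under 0.05 in either direction, where chance gives 1137.3.

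Values that did not pass in total RNA included Hop3, a co-chaperone, at −0.45 (SE 0.13), IMP4 at −0.61 (SE 0.20), ZCF125 at −0.49 (SE 0.18), BGLU25 at −0.40 (SE 0.15) and CP1 at −0.43 (SE 0.16) in gcn2, each with a limma adjusted p of 1. The gcn2 level of Hop3 (2.92) lay below the lower quartile of every array, so that its value is against a signal near background. On the other side 2A6 stood at 0.91 (SE 0.27), SAPX, an ascorbate peroxidase, at 0.73 (SE 0.28), ATGRIP at 0.55 (SE 0.20), NdhS at 0.40 (SE 0.15) and ATMPK8 at 0.39 (SE 0.15). The photosystem and light-harvesting proteins encoded in the nucleus were higher in 7 of 7 measured members, with a median of 0.13, among them PSAN at 0.38 (SE 0.16) and LHCB4.2 at 0.37 (SE 0.19). In limma 0 members passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The list passed camera (adjusted p = 0.00348) but not with an estimated correlation (adjusted p = 0.589). It was lost without wild-type total RNA replicate 3 (adjusted p = 0.544) or gcn2 total RNA replicate 1 (adjusted p = 0.0552), in a range of 4.82e-05 to 0.589 over all alternatives. The lists of plastid-encoded genes (median 0.11, adjusted p = 0.471), mitochondrion-encoded genes (−0.07), histones (−0.11), autophagy (−0.09) and anthocyanin synthesis (−0.04) did not pass, nor did amino acid biosynthesis (−0.04), the unfolded protein response (−0.06), the reactive oxygen response (−0.03), upstream open reading frame genes (0.04) or jasmonate and wounding, whose median of 0.04 and mean of −0.00 differ in sign. The plastid list passed as lower without wild-type replicate 1 (camera adjusted p = 3.88e-05) and as higher without wild-type replicate 3 (2.74e-13) or gcn2 replicate 2 (0.00123), and the mitochondrial list as lower without wild-type replicate 1 (0.0199) or gcn2 replicate 3 (0.0123). With an estimated correlation on all arrays the adjusted p values were 0.853 for the plastid and 0.833 for the mitochondrial list.

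The count of 8 in total RNA depended on some arrays and settings. It was 4 without gcn2 total RNA replicate 3 and 15 without wild-type total RNA replicate 2. It was 4 when only the 6 total RNA arrays were fitted, 3 without dim probe sets and 43 with array weights, of which 19 were higher and 24 lower. Fitting only these arrays, like the control centring, ended the calls of QQS (adjusted p = 0.712 and 0.124), AT3G30200, AT1G12000 and the unannotated probe set at 1.03. QQS lost its call without wild-type total RNA replicate 1 (adjusted p = 0.0614) or gcn2 total RNA replicates 1 (0.0556) and 3 (0.0712), as did AT3G30200 without gcn2 replicates 1 and 3 (0.0556 and 0.0712) and the probe set at 1.03 without gcn2 replicate 3. AT1G12000 lost its call without wild-type replicates 1 and 2 (0.166 and 0.0723) or gcn2 replicates 2 and 3 (0.0790 and 0.216). AT1G58025, AT1G35650, AT4G03156 and the unannotated probe set at 2.29 passed in all alternatives run for them. All of these but AT1G58025 were removed by the dim filter and have no value under it. The calls left there were AT1G58025, AT1G12000 and the probe set at 1.03.

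**Figure D1:**
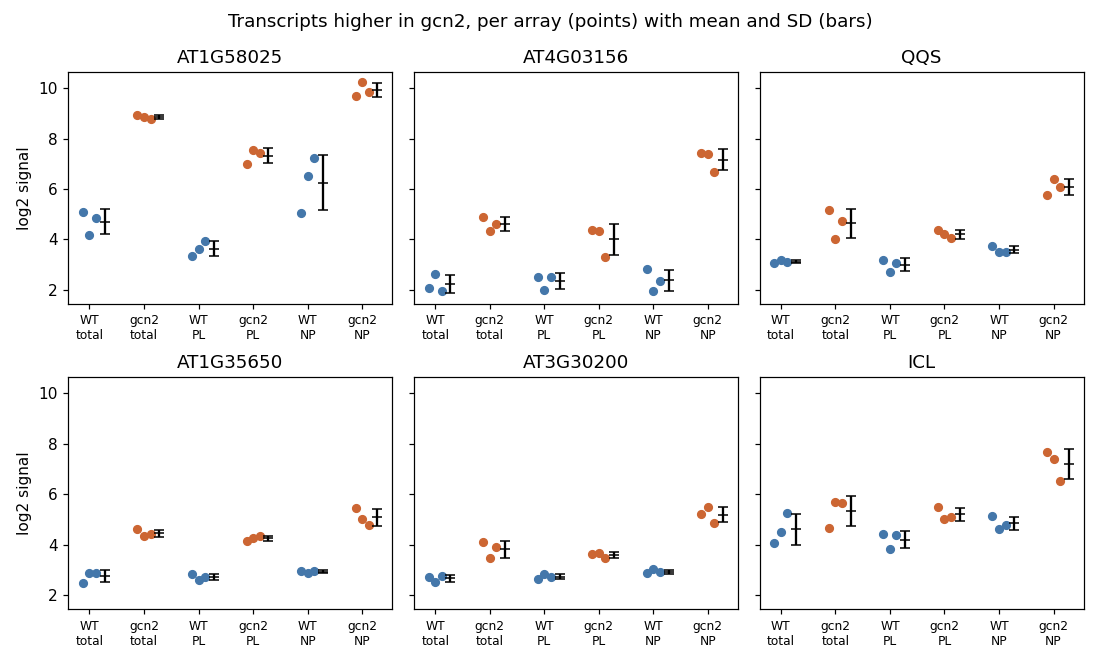
Log2 signal of transcripts that were higher in gcn2 than in wild type, by RNA type and genotype. Points are single arrays and bars are means of 3 arrays; AT1G58025 stood at 4.71 in wild-type and 8.85 in gcn2 total RNA.

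Polysome loading, the difference between polysomal and non-polysomal log2 signal, asked which transcripts lay toward the ribosome-bound part of the gradient in wild type. CYS1 (AT5G12140), a cysteine protease inhibitor, rose by 2.47 (SE 0.29), the dehydrins AtHIRD11 by 2.18 (SE 0.20) and COR47 by 1.92 (SE 0.21). GSA1, an enzyme of tetrapyrrole synthesis, rose by 2.05 (SE 0.18) and CLPP4, a subunit of the plastid Clp protease, by 1.99 (SE 0.22). PYK10 and BGLU33, both beta-glucosidases, rose by 1.81 (SE 0.20) and 1.76 (SE 0.15), TRXF2, a plastid thioredoxin, by 1.80 (SE 0.16), CRR21 by 1.79 (SE 0.26) and MAP1C, a methionine aminopeptidase, by 1.76 (SE 0.24). The drought-induced genes DI21 (AT4G15910) and DI19 (AT1G56280) fell by 2.90 (SE 0.31) and 2.58 (SE 0.32). The glyoxalase GLX2-5 fell by 2.44 (SE 0.23), the subtilase SBT3.12 by 2.18 (SE 0.38) and STOMAGEN, a peptide that promotes stomata, by 2.04 (SE 0.19). The mitochondrial nad1 fell by 2.03 (SE 0.26), CP5 by 1.99 (SE 0.25), HL by 1.94 (SE 0.21), and the plastid genes psbN and rpl32 by 3.11 (SE 1.13) and 1.93 (SE 0.55), each with n = 3 arrays per fraction and no overlap of the replicates.

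In limma, 6490 of 22746 probe sets passed in wild-type loading, 3468 higher and 3022 lower in polysomal RNA, and 1834 of them differed by at least 2-fold, 1150 higher and 684 lower. The adjusted p was 4.57e-06 for CYS1, 1.61e-06 for DI21 and 0.0466 for psbN. The psbN call was lost without wild-type polysomal replicates 1 (adjusted p = 0.199) and 2 (0.0862) and without non-polysomal replicates 2 (0.0801) and 3 (0.190). It was also lost with a trended and robust prior (0.111) and with quantile normalization within RNA type (0.0513). The psbN range was 2.40e-07 to 0.199 over all alternatives. The rpl32 call was lost without polysomal replicate 1 (0.0799) and non-polysomal replicate 3 (0.0565). All of these directions are relative to the array-wide level. How far they depend on that scale was tried with the hybridization controls, whose signal does not measure the RNA per fraction. When each array was centred on its BioB and BioC controls, a scaling chosen after seeing the data, the median of all probe sets moved from −0.07 to 0.86 in wild type and from −0.04 to 0.81 in gcn2. The shift is the same for every probe set, so that negative values smaller in size than the shift changed sign by construction, and the calls became 17065 higher and 176 lower in wild type and 15607 higher and 243 lower in gcn2.

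The comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined. Of the 10 measured autophagy genes 8 rose in wild-type loading, 9 when adjusted over the list alone, with a median of 0.76, and these were mostly ATG8 proteins, which coat the autophagosome membrane. ATG8D rose by 1.11 (SE 0.19), APG8A by 1.04 (SE 0.17), ATG8F by 0.90 (SE 0.18) and ATG8H by 0.73 (SE 0.14). Of the 8 histones 5 rose, over all genes and over the list alone, including HTB2 by 1.74 (SE 0.19), HTB4 by 1.53 (SE 0.17), HTB1 by 1.49 (SE 0.22) and HTB11 by 1.30 (SE 0.24). Of the 7 photosystem proteins 4 rose in both counts, PSBY by 1.35 (SE 0.15), LHCB4.3 by 1.11 (SE 0.26), PSAN by 0.75 (SE 0.16) and PSAE-1 by 0.57 (SE 0.11). Of the 6 genes of amino acid biosynthesis 4 rose, 5 over the list alone. They included BCAT4 and HISN5B, both at 0.92 (SE 0.17 and 0.18), OTC at 0.60 (SE 0.16) and IGPD at 0.54 (SE 0.15). BCAT4 is also a member of the glucosinolate list, so that its rise does not belong to amino acid biosynthesis alone. In the unfolded protein response 2 of 6 rose, 3 over the list alone, namely ATERDJ3B by 0.70 (SE 0.17) and CRT1b by 0.60 (SE 0.14).

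The camera adjusted p values were 5.42e-05 for autophagy, 2.50e-04 for histones, 0.00152 for photosystem proteins, 0.00501 for amino acid biosynthesis and 0.0386 for the unfolded protein response. With an estimated correlation the adjusted p values were 0.150, 0.106, 0.162, 0.106 and 0.162. The call of the unfolded protein response also ended without wild-type polysomal replicate 3 (adjusted p = 0.107) or non-polysomal replicate 1 (0.0571), with quantile normalization (0.230), without dim probe sets (0.173) and with the replicate number as a block on the 12 fraction arrays (0.0532). OTC and IGPD lost their calls without wild-type polysomal replicate 1 (adjusted p = 0.0642 and 0.0681), and OTC and CRT1b theirs with quantile normalization (0.0638 and 0.0578).

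Of 16 mitochondrion-encoded genes 6 fell in wild-type loading, 7 over the list alone, and 16 of 16 had negative values, with a median of −0.998. Leaving out dim probe sets kept only 7 of these 16 genes. Whether the arrays read plastid and mitochondrial transcripts in the same way as nuclear ones was not tested, here or in the other comparisons. Besides nad1, ccb452 fell by 1.36 (SE 0.35), cox2 by 1.24 (SE 0.18) and nad4L by 1.2 (SE 0.34), the last losing its call without polysomal replicate 1 (adjusted p = 0.0541) or non-polysomal replicate 3 (0.0780). Of the 69 plastid-encoded genes 5 fell, 4 over the list alone, and 58 had negative values, with a median of −0.97. Their spread between arrays was wide, with per-gradient medians of −1.72, −0.40 and −0.72. The mitochondrial list passed camera (adjusted p = 0.00152, and 0.289 with an estimated correlation), while the plastid list did not (adjusted p = 0.0941, and 0.758 with an estimated correlation). The plastid list passed with the replicate number as a block on 18 (adjusted p = 9.10e-05) or 12 arrays (3.67e-07), with quantile normalization (0.0155) and without dim probe sets (0.0266). It also passed without polysomal replicate 2 (0.0379) or 3 (0.00162) and without non-polysomal replicate 1 (0.0115), in a range of 3.67e-07 to 0.895 over all alternatives. With the control centring the mitochondrial and plastid list medians in wild type were near 0, at −0.06 and −0.03, and cox2, ccb452 and nad4L lost their calls. With the replicate number as a block, 13 mitochondrial members fell on 18 and on 12 arrays, and of the plastid members 31 fell and 2 rose on 18 arrays, and 43 fell and 4 rose on 12.

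The remaining lists did not pass camera in wild-type loading. They were anthocyanin and flavonoid synthesis (1 of 5 rose, adjusted p = 0.113), genes with conserved upstream open reading frames (1 of 6 rose and 1 fell, adjusted p = 0.196), jasmonate and wounding (1 of 5 rose, adjusted p = 0.214) and the reactive oxygen response (1 of 5 rose, adjusted p = 0.631), whose median of −0.04 and mean of 0.02 differ in sign. With the block on 12 arrays 3 anthocyanin and 2 upstream open reading frame genes rose. Among the latter PMEAMT rose by 1.28 (SE 0.20) and BZIP53 fell by 0.88 (SE 0.20). Lists with fewer than 5 measured members were not tested as sets. ILA, the plant homologue of the GCN2 activator GCN1, fell by 0.91 (SE 0.19) in wild type and by 1.09 (SE 0.19) in gcn2. EIF4A-2, an RNA helicase of translation initiation, rose by 0.50 (SE 0.13) and 0.66 (SE 0.13), the chaperone ATFKBP65 by 0.76 (SE 0.22) and 0.80 (SE 0.22), and the glucosinolate gene GSTU20 by 1.45 (SE 0.18) and 1.67 (SE 0.18), in wild type and gcn2. The symbol RPS13 in the list of cytosolic ribosomal proteins matched AT1G77750, a ribosomal protein of the organelle type, which stood at 0.45 (SE 0.23) in wild type and rose by 0.93 (SE 0.23) in gcn2. SAG101, of the defence list, stood at −0.29 (SE 0.14) and fell by 0.71 (SE 0.14), with polysomal levels below the lower quartile of every array in both genotypes. The test of neither difference passed (limma adjusted p = 0.978 and 0.952). ALATS, AKINBETA1, GI, UFO, CLV3, M17 and OLEO3, from the lists of aminoacyl-tRNA synthetases, carbon starvation, clock, meristem and seed markers, did not pass in either genotype, with wild-type values of −0.02, −0.19, 0.13, −0.05, −0.45, 0.11 and −0.20, where both wild-type levels of M17 and the polysomal ones of CLV3 and OLEO3 lay below that quartile. Nor did the heat shock genes Fes1A (−0.07) and HSA32 (−0.38) or the glucosinolate genes UGT74B1 (0.36) and AOP3 (0.29). Of the root markers PYK10 passed in both genotypes, at 1.21 (SE 0.20) in gcn2, and EXPA18 stood at 0.10 (SE 0.15) in wild type and rose by 0.45 (SE 0.15) in gcn2, without the test of their difference passing (limma adjusted p = 0.966). EXPA7 passed in neither, at −0.47 (SE 0.19) in wild type.

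**Figure D2:**
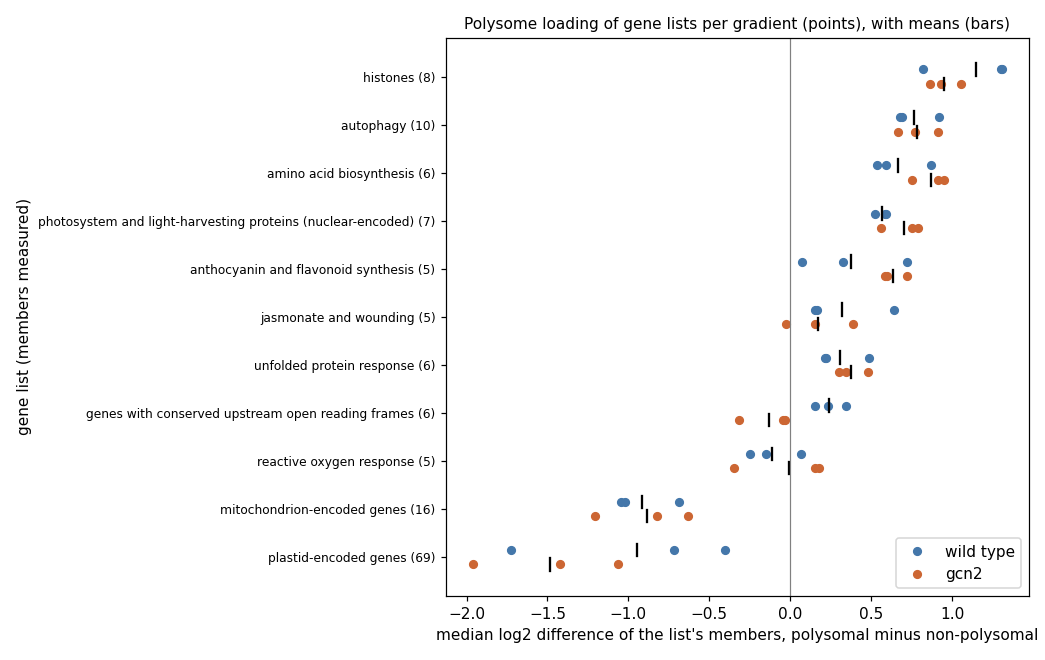
Median polysome loading (polysomal minus non-polysomal log2 signal) of the members of each gene list in the 3 wild-type and 3 gcn2 gradients. Points are gradients and bars are means of 3; the autophagy means are 0.76 in wild type and 0.78 in gcn2 and the plastid-encoded medians lie between −1.96 and −0.40, relative to the array-wide level.

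The same comparison in gcn2 gave 6492 calls in limma, 3443 higher and 3049 lower, with 1943 of at least 2-fold, 1141 higher and 802 lower. CLPP4 rose by 2.19 (SE 0.22), PDF1B, an organelle peptide deformylase, by 2.16 (SE 0.17), the dehydrins LTI30 by 2.09 (SE 0.37), AtHIRD11 by 1.96 (SE 0.20) and COR47 by 1.82 (SE 0.21). CYS1 rose by 2.02 (SE 0.29) and PRXIIF, a mitochondrial peroxiredoxin, by 1.95 (SE 0.14). COR15B, a cold-regulated plastid protein, rose by 1.79 (SE 0.28), Y14, of the exon junction complex, by 1.78 (SE 0.17) and FRO1 (AT5G67590), a subunit of respiratory complex I, by 1.74 (SE 0.15). DI21 fell by 3.24 (SE 0.31), DI19 by 2.65 (SE 0.32), SBT3.12 by 2.42 (SE 0.38) and GLX2-5 by 2.41 (SE 0.23). Further falls were those of CP5 by 2.13 (SE 0.25) and 2A6 by 2.04 (SE 0.27). The plastid genes clpP, petL, rpl32 and psbJ fell, with values of −2.67 (SE 0.81), −2.64 (SE 0.82), −2.58 (SE 0.55) and −2.31 (SE 0.75). The calls of clpP, petL and psbJ ended without gcn2 polysomal replicate 1 (adjusted p = 0.102, 0.102 and 0.131) and without non-polysomal replicates 2 and 3 (0.0560 to 0.0970). That of petL ended also without polysomal replicate 2 (0.0641). On all arrays the calls of clpP, petL and psbJ ended with a trended and robust prior (0.0603, 0.0658 and 0.0765).

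Of the gene lists, 8 passed camera in gcn2 loading with the preset correlation, and 0 with an estimated one (adjusted p = 0.115 to 0.664 for these 8). In autophagy 7 of 10 rose, 9 over the list alone (median 0.82, adjusted p = 1.36e-04). In the photosystem list 4 of 7 rose (median 0.64, adjusted p = 2.30e-04), and in histones 5 of 8 (median 0.95, adjusted p = 0.00124), with 1 fall over the list alone. In amino acid biosynthesis 5 of 6 rose and CBL fell by 0.63 (SE 0.17), with AT-HF at 1.48 (SE 0.30), HISN5B at 1.33 (SE 0.18), and BCAT4 and IGPD at 0.88 (SE 0.17 and 0.15, adjusted p = 0.00180). In the unfolded protein response 4 of 6 rose in both counts (adjusted p = 0.0368), and in anthocyanin and flavonoid synthesis 3 of 5 (adjusted p = 0.0312), 4 over the list alone, with UGT78D1 at 0.74 (SE 0.22) and UGT78D2 at 0.67 (SE 0.17). The symbol CHI in that list matched a chitinase (AT2G43570), which rose by 1.16 (SE 0.43). Of the mitochondrion-encoded genes 7 of 16 fell, 8 over the list alone (median −0.90, adjusted p = 0.00602), and of the plastid-encoded genes 11 of 69, 10 over the list alone (median −1.45, adjusted p = 6.96e-04), including ndhC by 1.07 (SE 0.16), rps4 by 1.31 (SE 0.24) and psbM by 1.51 (SE 0.28), of which ndhC and rps4 lost their calls under the control centring. With the replicate block 11 mitochondrial members fell on 18 and on 12 arrays, and 42 and 53 plastid members, while 1 plastid and 1 reactive oxygen gene rose on 12 arrays and 1 histone fell in both fits. Upstream open reading frame genes (adjusted p = 0.832), jasmonate (0.339) and reactive oxygen (0.808) did not pass, the last with a median of −0.01 and a mean of 0.03.

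With an estimated correlation the adjusted p values in gcn2 loading were 0.115 for the photosystem, histone and amino acid lists, 0.123 for autophagy and anthocyanin, 0.154 for the unfolded protein response, 0.398 for mitochondrial and 0.664 for plastid genes, so that no list passed. Without gcn2 non-polysomal replicate 3 the mitochondrial (adjusted p = 0.0530) and plastid lists (0.0692) lost their calls, the plastid list also without polysomal replicate 1 (0.107). The unfolded protein response and anthocyanin lists lost theirs without polysomal replicate 3 (0.0623 and 0.0601) or non-polysomal replicate 1 (0.10 and 0.0638), and the unfolded protein response also with the replicate block on 12 arrays (0.0637), with quantile normalization (0.199) and, like the mitochondrial list (0.0782) and anthocyanin (0.111), without dim probe sets (0.131). Among members, CHI lost its call without 5 of the 6 arrays, all but polysomal replicate 1 (0.0640 to 0.180). The CHI call also ended with a trended and robust prior (0.0911) and with the block of genotype and number together (0.0580). UGT78D1 lost its call without polysomal replicate 3 (0.0502) or non-polysomal replicate 3 (0.109). In the unfolded protein response BZIP28 lost its call without polysomal replicates 2 and 3 (0.0665 and 0.0560) or non-polysomal replicates 1 and 3 (0.0876 and 0.0523), BZIP17 without any array but non-polysomal replicate 2 (0.0771 to 0.120), and BZIP17 and CRT1b with only the compared arrays (0.0758 and 0.0531) or quantile normalization (0.0710 and 0.162). The BZIP17 call also ended with a trended prior (0.0689), array weights (0.0797) and the block of genotype and number together (0.0541). Of the mitochondrial members, nad1 (−0.47, adjusted p = 0.158), ccb452 (−0.32, 0.347), nad6 (−0.09, 0.773) and cox2 (−0.07, 0.820) lost their calls under the control centring. The calls of ccb452 and nad6 also ended without polysomal replicate 1 (0.0834 and 0.0550) or non-polysomal replicate 3 (0.113 and 0.117), and that of nad6, whose polysomal level lay below the lower quartile of every array, without polysomal replicate 3 (0.0526).

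Loading in both genotypes was alike across probe sets. The values of the 22746 probe sets correlated at 0.89 (Pearson) and 0.80 (Spearman), over probe sets that are not independent replicates and from arrays that the comparisons do not share. Of 4732 probe sets called in both genotypes, 4730 had the same direction, 2729 higher, where independent lists give 525, and 2001 lower, where they give 405.

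The difference in loading between gcn2 and wild type asked which transcripts changed their place in the gradient in the mutant. The control transcripts' 3′ excess in non-polysomal over polysomal RNA was larger in gcn2 by 0.40, in the means of 3 gradients. An exact two-sided permutation test of 3 against 3 gradients gave p = 0.2, where the smallest possible is 0.1. Whether this excess affected the values below was not tested. The only call among 22746 probe sets was AT4G03156, chosen after its values were seen, with a value of −3.13 (SE 0.42, n = 3 gradients per genotype, limma adjusted p = 0.0135). Its polysomal and non-polysomal levels were 4.00 ± 0.62 and 7.17 ± 0.43 in gcn2 and 2.34 ± 0.31 and 2.37 ± 0.43 in wild type (SD, n = 3 each). The wild-type levels lay below the lower quartiles of the arrays (3.21 to 3.52), near their lowest signals. Its wild-type loading was therefore not measured, and the value sets gcn2 loading against background. No transcript was called with higher loading, and 1150 probe sets had an unadjusted p under 0.05, where chance gives 1137.3. The replicate block on the 12 fraction arrays gave 2038 such probe sets. The smallest p values with higher loading in gcn2 were those of SCPL32 at 0.87 (SE 0.20, adjusted p = 0.661), ATOEP16-4 at 0.66 (SE 0.17), BSH at 1.05 (SE 0.28), UGT85A3 at 0.79 (SE 0.21) and LEA4-5 at 0.96 (SE 0.28). Those with lower loading were QQS at −1.27 (SE 0.31, adjusted p = 0.661), CYP71B36 at −0.58 (SE 0.17), SPT at −0.54 (SE 0.16), NRPA1 at −0.94 (SE 0.30) and scpl46 at −0.60 (SE 0.20), none of which passed. QQS in wild-type polysomal RNA and CYP71B36 in all groups but gcn2 non-polysomal RNA lay below the lower quartile of every array as well.

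The AT4G03156 value lost its call without wild-type polysomal replicates 1 and 3 (adjusted p = 0.0690 and 0.0717), wild-type non-polysomal replicates 2 and 3 (0.0792 and 0.0653) and gcn2 non-polysomal replicates 1 and 2 (0.0789 and 0.0942), with values from −3.13 to −2.92. Without gcn2 non-polysomal replicate 3 the count was 2, and without dim probe sets it was 0. AT4G03156 also lost its call when only the 12 fraction arrays were fitted without a block (0.0797), and stood at −0.71 (adjusted p = 0.975) as polysomal over total RNA, in a range of 9.38e-04 to 0.975 over all alternatives. With the replicate number as a block on the 12 fraction arrays, 3 probe sets were called, 1 higher and 2 lower.

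The genes with conserved upstream open reading frames, whose main coding sequence follows a translated short one, had lower loading in gcn2 in 5 of 6 members, with a median of −0.45. bZIP44 stood at −0.61 (SE 0.26), BZIP53 at −0.52 (SE 0.28), SAMDC, which makes a precursor of polyamines, at −0.47 (SE 0.28) and PMEAMT, of choline synthesis, at −0.44 (SE 0.28). Their median loading per gradient was 0.24 ± 0.10 in wild type and −0.13 ± 0.16 in gcn2 (SD, n = 3 each). Of the other members, ATB2 (−0.08) matched a gene other than the one meant and EIN3 (0.05) was placed on the list in error. The plastid-encoded genes had lower loading in gcn2 in 65 of 69 members, with a median of −0.46 and gradient medians of −0.95 ± 0.69 in wild type and −1.48 ± 0.45 in gcn2 (SD, n = 3 each). The members moved together (estimated inter-gene correlation of 0.87), so that their count is not one of independent genes. By number, the medians in wild type and gcn2 were −1.72 and −1.42 for number 1, which was higher in gcn2, −0.40 and −1.96 for number 2 and −0.72 and −1.07 for number 3. In limma 0 members of either list passed, over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 there were 1 in the first and 0 in the second.

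Both lists had a camera adjusted p of 0.0107 for the difference in loading. With an estimated correlation the adjusted p was 0.271 for the upstream open reading frame genes and 0.942 for the plastid-encoded genes, and with the replicate block it was 0.0144 and 6.10e-07. Without ATB2 and EIN3 the first list held 4 members and was not tested as a set. It lost its call without wild-type non-polysomal replicate 1 (adjusted p = 0.169), gcn2 polysomal replicate 1 (0.159) and gcn2 non-polysomal replicates 2 (0.135) and 3 (0.113), and without dim probe sets (0.0505). The plastid list lost its call without wild-type polysomal replicates 2 (0.0736) and 3 (0.760), wild-type non-polysomal replicates 1 (0.471) and 2 (0.0986), gcn2 polysomal replicate 1 (0.937, with camera's direction turned to higher), gcn2 non-polysomal replicates 2 (0.238) and 3 (0.867), and without dim probe sets (0.0706). The ranges over all alternatives were 9.40e-04 to 0.271 and 1.38e-11 to 0.942. Histones passed in the lower direction without wild-type polysomal replicate 3 (0.0301), with an adjusted p of 0.749 on all arrays with an estimated correlation. The other lists did not pass, with adjusted p values from 0.334 for photosystem proteins and histones to 0.930 for the unfolded protein response. The test pointed down where median and mean were positive for the unfolded protein response (0.01 and 0.01) and jasmonate (0.10 and 0.02), and the reactive oxygen response had a median of −0.07 and a mean of 0.02.

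Polysomal RNA of gcn2 was compared with that of wild type to find transcripts that differed in amount among ribosome-bound RNA. AT1G58025 rose by 3.69 (SE 0.37, limma adjusted p = 1.65e-04), AT1G35650 by 1.53 (SE 0.16), the pseudogene AT1G42705 by 1.37 (SE 0.22), AT1G12000 by 1.25 (SE 0.17) and an unannotated probe set by 1.01 (SE 0.15), all chosen after their values were seen and higher in 3 of 3 arrays. With 3 arrays per group, these were the 5 calls in limma, and 1225 probe sets had an unadjusted p under 0.05. With the replicate number as a block on the 12 fraction arrays 2400 did, where chance gives 1137.3. Values that did not pass included QQS at 1.22 (SE 0.22, adjusted p = 0.108), 2A6 at 1.41 (SE 0.27), the late embryogenesis gene LEA4-5 at 1.01 (SE 0.20), the cold-regulated gene COR15A at 1.15 (SE 0.26) and ATOEP16-2 at 0.54 (SE 0.11). On the lower side stood the defensin PDF1.4 at −1.11 (SE 0.29), the linker histone HIS1-3 at −1.10 (SE 0.31), TBL40 at −0.52 (SE 0.14), PWD at −0.44 (SE 0.13) and AAPT2 at −0.42 (SE 0.12). M17, a seed-stage transcript, stood at 3.07 (SE 0.82, adjusted p = 0.589). The wild-type levels of AT1G35650 (2.73), QQS (2.99) and M17 (2.96) lay below the lower quartile of every array. The value of AT1G35650, which passed, is therefore a lower bound. Those of QQS and M17, which did not pass here, set gcn2 signals against signals near background and are no bounds. The SD of M17 was 1.13 in wild-type and 1.22 in gcn2 polysomal RNA. Both levels of ATOEP16-2 lay below that quartile too, so that its value measures no fold.

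The replicate numbers paired the fraction arrays but not gcn2 total RNA, which the block on 18 arrays pairs as well. With this limit, the block is given beside these counts. It called 15 probe sets over 18 arrays, 13 higher and 2 lower, with QQS (adjusted p = 0.0483), LEA4-5 (0.0353) and COR15A (0.0353) among them. It called 127 over the 12 fraction arrays, 67 higher and 60 lower, with M17 (SE 0.18), LEA18 at 1.51, ICL at 1.00, 2A6 (adjusted p = 3.20e-04), PDF1.4 (0.0116) and HIS1-3 (0.00824). All 5 calls held in both. The count of 5 became 140 with array weights, 89 higher and 51 lower, and 2 without wild-type polysomal replicate 2, 3 without gcn2 polysomal replicate 1 or 2. AT1G42705 lost its call without any 1 of the 6 arrays (adjusted p = 0.0618 to 0.336), the unannotated probe set without wild-type replicate 2 (0.0991) or any gcn2 replicate (0.0660 to 0.0792), and AT1G12000 without wild-type replicate 2 (0.0774). The control centring moved the median of all probe sets from 0.02 to −0.23 and ended the calls of AT1G35650 at 1.27 (adjusted p = 0.344), AT1G12000, AT1G42705 and the unannotated probe set.

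Autophagy genes were lower in gcn2 polysomal RNA in 10 of 10 members, with a median of −0.28. ATG8E stood at −0.97 (SE 0.31), ATG8F at −0.53 (SE 0.18), APG8A at −0.45 (SE 0.17) and ATG8B at −0.40 (SE 0.20), where 0 members passed over all genes in limma and 3 fell when adjusted over the list alone. With the block on 12 arrays ATG8E fell (adjusted p = 0.0229). Genes of amino acid biosynthesis were higher in 6 of 6 measured members, where the list names 97 loci. Their median was 0.33, with OTC at 0.45 (SE 0.16) and IGPD at 0.35 (SE 0.15), without a call by either count and with 2 at an unadjusted p under 0.05. The plastid-encoded genes were lower in 59 of 69 members, with a median of −0.32 and no member called by either count or at an unadjusted p under 0.05, while with the block on 12 arrays psbJ fell by 0.83 (SE 0.15, adjusted p = 0.0119). The camera adjusted p values were 4.26e-07, 0.00868 and 0.00868, and with an estimated correlation the adjusted p values were 0.102, 0.102 and 0.838. The plastid list lost its call without wild-type polysomal replicates 2 (adjusted p = 0.125) and 3 (0.436) and gcn2 polysomal replicate 1 (0.108), and without dim probe sets (0.103). Camera's direction for it turned to higher without wild-type replicate 3 or gcn2 replicate 1. Upstream open reading frame genes (median −0.30, adjusted p = 0.0740) passed with the block on 12 arrays (0.0261) and without wild-type polysomal replicate 1 (0.0483) or gcn2 polysomal replicate 2 (0.0299), and anthocyanin genes (median 0.30, adjusted p = 0.0886) without wild-type polysomal replicate 1 (0.0483) or with quantile normalization (0.0486). With an estimated correlation on all arrays the adjusted p was 0.252 for both. Without wild-type polysomal replicate 3 the histones passed in the lower direction (0.0187) and the mitochondrial genes in the higher (0.0359), where the adjusted p values with an estimated correlation on all arrays were 0.740 and 0.838. Adjusted over the list alone, 1 photosystem gene rose and 1 histone fell, and with the block on 12 arrays LHCB4.3 rose (0.0105) and HIS1-3 fell over all genes. The unfolded protein response had a median of 0.01 and a mean of −0.01.

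Non-polysomal RNA of gcn2 against wild type gave the most calls of the 3 RNA types. In this fraction the control transcripts also had a larger mean 3′ excess in gcn2 (3.72 ± 0.42) than in wild type (3.24 ± 0.31, SD, n = 3 each). The arrays overlapped, with 3.60 in wild-type replicate 1 and 3.39 in gcn2 replicate 3. Whether this excess affected the calls was not tested. AT4G03156 rose by 4.79 (SE 0.30, limma adjusted p = 7.62e-08), AT1G58025 by 3.66 (SE 0.37), an unannotated probe set by 2.68 (SE 0.26), QQS by 2.49 (SE 0.22, adjusted p = 8.83e-06), and ICL, the isocitrate lyase of the glyoxylate cycle, by 2.34 (SE 0.33). AT3G30200 rose by 2.26 (SE 0.17), AT1G35650 by 2.15 (SE 0.16), AT1G35612 by 1.87 (SE 0.21), 2A6 by 1.85 (SE 0.27), AT1G42705 by 1.82 (SE 0.22) and AT1G12000 by 1.1 (SE 0.17). AT3G27473 was called higher too, with both levels (2.18 in wild type and 2.96 in gcn2) below the lower quartile of every array, so that no size is given. AT1G51730 fell by 0.74 (SE 0.13) and AT2G34590 by 0.71 (SE 0.12), and 4 unannotated probe sets had values of −1.33 (SE 0.23), −0.88 (SE 0.13), −0.76 (SE 0.14) and −0.62 (SE 0.11). Below that quartile lay the wild-type levels of AT4G03156 (2.37), AT1G35612 (2.70), AT1G35650 (2.93), AT3G30200 (2.93) and the unannotated probe set at 2.68 (3.16), and the gcn2 level of the probe set at −0.76 (2.98). These 6 values are therefore lower bounds of the change. Those without a symbol were chosen after their values were seen. Values on the lower side that did not pass were ATRBP45C at −0.85 (SE 0.17, adjusted p = 0.0587), UBC28 at −0.85 (SE 0.20), WLIM2b at −0.76 (SE 0.15), BAT1 at −0.69 (SE 0.15) and PDF1.4 at −1.26 (SE 0.29).

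In limma these were 18 calls with 3 arrays per group, 12 higher and 6 lower, and 2603 probe sets had an unadjusted p under 0.05. With the replicate number as a block on the 12 fraction arrays 3954 did, where chance gives 1137.3. The replicate block called 62 over 18 arrays, 29 higher and 33 lower, among them UBC28 (adjusted p = 0.0336), WLIM2b (0.0382) and ATRBP45C (0.0417). It called 429 over the 12 fraction arrays, 190 higher and 239 lower, among them PDF1.4 (0.00556), AKINBETA1 (0.0136), HIS1-3 (0.0148), WLIM2b (0.0148) and ATRBP45C (0.0186). The 18 held in both. The split moved with the scaling, to 29 higher and 27 lower after quantile normalization of all arrays, 17 and 16 after normalization within each RNA type, 15 and 22 after median centring and 10 and 0 after control centring, which moved the median from 0.01 to −0.16. Without wild-type non-polysomal replicate 1 the count became 110, 32 higher and 78 lower, without wild-type replicate 2 it became 12, and without dim probe sets 7. All 6 lower calls and those of AT3G27473 and AT1G12000 ended when only the non-polysomal arrays were fitted, and under the control centring. The values themselves did not change in the first fit. Under the centring the lower ones grew in size, to between −0.79 and −1.49, and AT3G27473 and AT1G12000 stood at 0.61 and 0.93. Each also failed without at least 1 array, AT1G51730 without 5 of 6 (adjusted p = 0.0655 to 0.167). AT1G12000 was lost without gcn2 replicate 2 (0.0509).

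Autophagy was again lower in gcn2, in 9 of 10 members of non-polysomal RNA with a median of −0.36. ATG8E stood at −0.88 (SE 0.31) and ATG8C at −0.64 (SE 0.19), where 0 members passed over all genes in limma, 1 fell when adjusted over the list alone, and 5 had an unadjusted p under 0.05. With the block on 12 arrays ATG8E fell (adjusted p = 0.0281). The list passed camera (adjusted p = 6.02e-04) and not with an estimated correlation (adjusted p = 0.724). Plastid-encoded genes (median 0.18, adjusted p = 0.522) were called higher with the block on 12 arrays (0.0258) and without wild-type non-polysomal replicate 3 (0.00166) or gcn2 non-polysomal replicate 1 (8.48e-07), although psbK was the only member called with that block, as lower, at −0.68 (0.0418). Upstream open reading frame genes (median 0.17, adjusted p = 0.472) were called higher without gcn2 non-polysomal replicate 1 (0.0295), and with the block on 12 arrays PMEAMT rose by 0.72 (0.0299). For both lists the adjusted p with an estimated correlation on all arrays was 0.920. The other lists did not pass. Signs differed for anthocyanin (median −0.04, mean 0.08), jasmonate (median 0.10, mean −0.09) and reactive oxygen genes (median −0.00, mean 0.08).

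The transcripts called against wild type overlapped between RNA types. Total and polysomal RNA shared 4 calls (two-sided Fisher's exact test, p = 3.14e-14), total and non-polysomal RNA 7 (p = 4.08e-22), and polysomal and non-polysomal RNA 4 (p = 1.37e-12), all in the same direction, and AT1G58025, AT1G35650 and AT1G12000 were the 3 called in each RNA type. These tests take probe sets as independent. The calls also share each probe set's estimate of spread, so the p-values do not measure replication across samples. Over all probe sets, the genotype differences of polysomal and non-polysomal RNA correlated at 0.37, and those of total RNA at −0.07 with polysomal and 0.08 with non-polysomal RNA, across probe sets that are not independent replicates.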

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

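The tests of a linked genome segment, of pseudogenes, of a mislabelled array, of the total RNA numbering and of the common scale were chosen after the result was seen.

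The BioB and BioC controls were higher on non-polysomal than on polysomal arrays by 0.89 on the log2 scale, a signal in probe sets outside the comparisons. The 3′ excess of the control transcripts was larger on the fraction arrays than on the total RNA arrays by 0.97. The test of the difference in loading called AT4G03156 at −3.13, but with both wild-type fractions near the lowest signals of the arrays its wild-type loading was not measured. Of the gene lists, camera with the preset correlation called the genes with conserved upstream open reading frames (median −0.45) and the plastid-encoded genes (median −0.46). In limma 0 members of either list passed. In the first list ATB2 was mismatched and EIN3 placed in error, and without them it was too short to be tested. Neither list passed with an estimated correlation (adjusted p = 0.271 and 0.942). The plastid call ended in 7 of the 12 fits that each left out 1 fraction array, with camera's direction turned to higher without gcn2 polysomal replicate 1.

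The first pattern is the set of transcripts higher in gcn2 in total RNA and in the fractions, such as AT1G58025. At most 4 of the 11 loci called higher lay within any stretch of 500 neighbouring measured loci, and the 11 were spread over 3 chromosomes, which argues against a single linked segment from another line as the whole source and leaves it open for those 4. A mislabelled array is argued against, since 0 arrays lay outside their genotype's range in the mean of the transcripts called higher on the arrays of the other RNA types alone. Pseudogenes made up 27.3% of the 11 loci and 7.43% of the others (two-sided Fisher's exact test, p = 0.0432, and p = 0.0670 with the 2 lower loci included), so pseudogenes expressed in gcn2 may be part of the pattern, although these are 3 loci, 2 of them read by probe sets of a kind shared between similar sequences. Several unlinked segments and an effect of the gcn2 mutation itself were not tested and stay open.

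The second pattern is that genotype differences correlated between polysomal and non-polysomal RNA (0.37) and not with total RNA. Plant preparations shared by both fractions of a number could give this, and the differences of the same number correlated at a mean of 0.263 (0.185 to 0.396, with 3 of 3 pairs above 0.1), but those of different numbers also did, at a mean of 0.145 with 4 of 6 pairs above 0.1, which neither excludes nor singles out that explanation. Whether total RNA came from other preparations than the fractions of its number stays open too, since all 3 same-number correlations were above 0.1 in 3 of 8 pairs of a total RNA and a fraction group, 3 of 4 for wild-type and 0 of 4 for gcn2 total RNA. gcn2 total replicate 2 correlated with number 1 of the polysomal arrays (0.470 in gcn2 and 0.445 in wild type), and gcn2 total replicates 1 and 2 with wild-type total replicates 2 and 1 (0.311 and 0.237, against 0.0981 and 0.0157 at the same number), so those numbers may be exchanged, which would leave the group means as they are. An effect of gcn2 limited to the gradient fractions was not tested apart from these.

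The third pattern is that about as many transcripts were lower as higher in loading, among calls without a fold threshold. At 2-fold more were higher, 1150 against 684 lower in wild type and 1141 against 802 in gcn2. The arrays' common scale could produce the balance and cannot be told apart from a true one. The hybridization controls differed by 0.89 between the fractions, but the sources used here give neither the step at which they were added nor the amount. Their signal therefore does not measure the RNA per fraction. Shorter RNA in the non-polysomal fraction stays open as well: a correlation above 0 of loading with the response to the 3′ excess, across probe sets that are not independent replicates, had been set in advance to exclude it, which the Pearson value met (0.0618, and 0.0237 to 0.0890 with each array left out), but that bound named no kind of correlation and the Spearman value did not meet it (−0.00623, and −0.0430 to 0.0190), while in gcn2 the values were 0.115 and 0.0416. The 3′ excess was larger in non-polysomal RNA by 0.53 in the mean, in 5 of 6 gradients (exact two-sided sign-flip test, p = 0.0625), and loading at the 5′ and 3′ ends was 1.90 and 1.1 for the GAPDH control, 1.12 and 0.81 for ubiquitin and 0.71 and 0.81 for Actin in wild type, and 2.01 and 0.74, 1.18 and 0.59, and 0.98 and 0.63 in gcn2. No biological explanation was tested.

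Each comparison of 3 against 3 has 10 splits of its arrays or gradients, too few for a share under 0.05. As many calls as the real one came from 1 split, the real one, in total RNA (8 against a highest other of 0), wild-type loading (6490 against 0), gcn2 loading (6492 against 0), the difference in loading (1 against 0), polysomal RNA (5 against 0) and non-polysomal RNA (18 against 1). Among the 4 splits that part as many pairs, the highest other was 0 in each of these. For the gene lists, as many calls came from 10 splits in total RNA (1 against 5), 3 in wild-type loading (6 against 7), 1 in gcn2 loading (8 against 5), 1 in the difference (2 against 1), 6 in polysomal RNA (3 against 5) and 9 in non-polysomal RNA (1 against 3). Against the splits that part as many pairs, the highest other list counts were 2, 4, 4, 1, 3 and 2 in that order, and the remaining splits mix arrays of a number differently.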

How the results depend on the processing

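The control centring, the replicate block on 12 arrays and the lists without mismatched members were chosen after the result was seen. Of 3496 values of named genes under alternatives, 3251 kept direction and side of the threshold, 164 fell short of it, 80 newly passed, and 1 turned, PMEAMT in the difference in loading, at 0.16 as polysomal over total RNA (adjusted p = 0.986). Of those newly passing, 34 came from the block on 12 arrays, by which many of these genes had been chosen. The 3251 include genes that passed in neither fit, and genes removed by the dim filter have no value there. Where not said otherwise, the cause was not tested.

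Total RNA gave 8 calls, 4 with only the compared arrays (fewer arrays to estimate the spread), 3 without dim probe sets, 43 with array weights and 4 with control centring, and 4 to 15 with each array left out. Loading gave 17241 calls in wild type and 15850 in gcn2 with control centring, whose shift of all probe sets makes most calls higher, 1834 and 1943 at 2-fold, and 5014 to 5918 and 5359 to 5964 with each array left out. The difference in loading gave 0 with only the compared arrays, 0 without dim probe sets and 0 as polysomal over total RNA, and 0 to 2 with each array left out, where 1150 probe sets had an unadjusted p under 0.05 in limma on all arrays. With the replicate block on the 12 fraction arrays that number was 2038, where chance gives 1137.3. Polysomal RNA gave 140 with array weights and 2 to 6 with each array left out. Non-polysomal RNA gave 56 and 33 with quantile normalization over all arrays and within RNA types, 37 with median centring, 7 without dim probe sets, 10 with control centring, and 12 to 110 with each array left out, the highest without wild-type replicate 1. Low signal limits the dim probe sets, AT4G03156 in wild type among them.

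The replicate block on 18 arrays gave 8 calls in total RNA, 7415 and 7244 in wild-type and gcn2 loading, 1 in the difference, 15 in polysomal and 62 in non-polysomal RNA, and on the 12 fraction arrays 8381, 8180, 3, 127 and 429. Beyond the blocked values given beside the results, it changed no list call on 18 arrays other than that of plastid-encoded genes in wild-type loading, and on 18 arrays no call of a list member in the genotype comparisons of the fractions or the difference in loading. In non-polysomal RNA 2 lists were called with the block on 12 arrays.

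With an estimated correlation 0 lists were called in total RNA, 0 in wild-type loading, 0 in gcn2 loading, 0 in the difference, 0 in polysomal and 0 in non-polysomal RNA, against 1, 6, 8, 2, 3 and 1 with the preset one in camera. Without dim probe sets 5 lists were called in gcn2 loading and 0 in the difference, and without mismatched members 1 in the difference, as the upstream open reading frame list fell under 5 members. With each array left out, the lists called numbered 0 to 3 in total RNA, 6 to 7 and 6 to 8 in loading, 0 to 2 in the difference, 2 to 5 in polysomal and 1 to 3 in non-polysomal RNA.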

Other observations

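The families named here and the test of their difference in loading were chosen after the result was seen.

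Vacuolar protein sorting genes, which include subunits of the machinery that buds vesicles into endosomes, went both ways in loading. Of 12 measured members 6 rose and 2 fell in each genotype, with medians of 0.40 in wild type and 0.46 in gcn2. VPS24.1 rose by 1.35 and 1.68, VPS46.2 by 1.11 and 1.32 and VPS2.1 by 1.04 and 1.21, while VPS20.1 fell by 0.54 and 0.74 and VPS9B by 0.82 and 0.51. The family did not pass camera in either genotype (adjusted p = 0.308 and 0.366 over 21 families), nor did any other. Every split reaches a count of 0, so that the splits, of which 10 of 10 did so in each genotype with a highest other of 2 and 1, decide nothing here.

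IQ-domain proteins, which bind calmodulin, had lower loading in gcn2 in 10 of 11 members, with a median of −0.27, and 0 members passed in limma. IQD31 stood at −0.67, IQD30 at −0.64 and IQD24 at −0.49. The family passed camera for the difference (adjusted p = 0.00103, and adjusted p = 0.0233 with an estimated correlation), and ubiquitin-specific proteases, with a median of −0.26 over 12 members, passed with the preset correlation only (adjusted p = 0.0381, and adjusted p = 0.406 with an estimated correlation). Only the real split, 1 of 10, called 2 families, with a highest other of 1, and 10 splits are too few for a share under 0.05. For the families no fit with an array left out, without dim probe sets or with other normalization is given here. How far these 2 calls depend on single arrays is therefore not known.

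Gene length and loading were nearly unrelated over 13285 of 13355 loci, with a Spearman correlation of 0.06 in wild type and −0.04 in gcn2, across genes that are not independent replicates.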
